A study of Mus musculus with 10 samples.

How the data were processed

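Gene expression was measured on 10 arrays, 2 for each of 5 mouse mammary tumour cell lines. Line E is an epithelial line from a spontaneous mammary adenocarcinoma of a female MMTV-neu mouse, a strain in which the neu oncogene (Erbb2) is driven in the mammary gland by a viral promoter. Lines M1, M2, M3 and M4 are mesenchymal lines, each from a tumour that relapsed after E cells had been injected into female FVB/N mice. Per the labels, all cells were grown in RPMI medium with serum to near confluence, total RNA was isolated on columns, and biotin-labelled cRNA was hybridized. Whether the 2 arrays of a line came from separate cultures or from the same RNA is not given in the sources used here.

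The deposited values are probe set signals in units of intensity on a linear scale, with 45101 probe sets per array, no missing value, 9 values of 0 and a highest value of 18694.5. The submitters' processing notes name GCOS 1.3; the signal algorithm, the scaling target and any background correction are not given in the sources used here. Detection calls were not used here. The array type has hybridization and labelling controls, 64 control probe sets in all, and these were left out of the tests. By the symbols paired with the probe sets, 34945 had a single gene symbol, 932 several and 9160 none. Of those with a single symbol, 34741 had a gene number found in the mouse gene table, and no symbol needed an update. They stood for 18193 genes.

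The arrays were not on a common scale. The trimmed mean signal ran from 299 on E replicate 1 to 181 on M4 replicate 1, and the geometric mean of 9 hybridization controls ran from 1648 to 1067 on the same arrays. The deposited scaling was kept for the reported values, as had been fixed before the data were examined; other scalings were run as alternatives.

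A pseudocount of 32 was added and values were taken to log2. A probe set was kept when it lay above its array's 40th percentile on at least 2 arrays, which 32978 did. Each gene was represented by its kept probe set with the highest mean, which left 14840 genes. Of 130 results for named genes, 70 were of genes with several probe sets; in 23 of these some probe sets were called and others were not, and in 0 were they called in opposite directions. The model was fitted with limma 3.58.1 in R 4.3.3: 1 mean per line, lmFit and eBayes with a trend in the prior. The 5 lines shared 1 estimate of the spread between the 2 arrays of a line, with 5 residual degrees of freedom, 41.1 prior degrees of freedom and a median residual SD of 0.174. A gene was called when its Benjamini-Hochberg adjusted p over all 14840 genes was under 0.05 and its change was at least 2-fold. "Rose" and "fell" refer to calls. Where a signal is near the background in 1 group, the size of the log2 change depends on the pseudocount.

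The contrasts were the mean of the 4 M lines minus E, each M line minus E, the 6 differences between M lines, each M line minus the mean of the other 3, and a moderated F test across the M lines. All p-values measure only the spread between the 2 arrays of a line, which may be technical. With 1 epithelial line, no test covers variation among epithelial lines. As a check at the level of lines, the mean contrast was also fitted by limma to 5 line means, with 3 residual degrees of freedom. The number of arrays limits the precision of every value.

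A total of 23 gene lists were fixed before the data were examined: epithelial adhesion and polarity, luminal mammary epithelium, basal and myoepithelial mammary epithelium, mesenchymal and extracellular matrix, EMT (epithelial-mesenchymal transition) transcription factors, ERBB receptors and ligands, mammary stem and progenitor markers, MHC class I antigen presentation, interferon response, TGF-beta signalling and targets, matrix proteases and inhibitors, cell cycle, CDK inhibitors and p53 targets, drug efflux transporters, DNA repair, Wnt signalling, glycolysis and hypoxia, cytokines and chemokines, and markers of leukocytes, endothelium, adipocytes, stromal fibroblasts and skeletal muscle. Of their 522 symbols, 487 had a probe set with that single symbol. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with limma's fry, adjusted over the lists. The camera test asks whether a list moved more than the other genes; fry asks whether its members moved, on balance, in 1 direction. Members were called over all genes and also adjusted over the list alone.

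The genes named were chosen by a rule fixed before the data were examined. It took 16 markers whatever their result (Cdh1, Epcam, Krt8, Krt18, Krt14, Vim, Fn1, Cdh2, Snai1, Snai2, Twist1, Zeb1, Zeb2, Erbb2, Cd44 and Cd24a). It took the 12 highest and 12 lowest changes of the mean contrast among genes called in it and in each of the 4 lines in that direction, leaving out probe sets of several symbols and symbols that are only clone or locus numbers. It took from each list up to 4 called members with the largest change, or up to 2 with the smallest p when none was called. It took for each M line the 3 highest and 3 lowest changes against the other 3 among genes called there and against each of them. Symbols that are only clone or locus numbers were left out of this choice too, but not of the counts of such genes. A few further members are named and marked as chosen after their values were seen.

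The pipeline was tested on simulated data for the mean contrast, in 20 runs with 14840 genes and 50 changed genes per fold size. It called 0.4% of genes changed 1.5-fold, 44.1% at 2-fold and 86.9% at 3-fold and at 4-fold. All genes raised 3-fold or 4-fold were called, and no unchanged gene was called in any run (0.0502% were without the fold minimum). In the simulated lists, a list shifted by 0.5 was called in 20 of 20 runs and no other list was. The simulated genes varied independently of each other and the simulated arrays had a common scale. In the real arrays the scale differed, and the members of a list had estimated correlations of up to 0.743. The absence of false calls therefore holds only for the simulated setting.

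Alternatives covered a smaller pseudocount (1) and a larger one (4 times as large), values below 64 set to 64, quantile normalization, median centring, the filter, the choice of probe set, the variance prior, a replicate block, the call, and leaving out each array in turn. Added after the data were seen were scaling to the hybridization controls, list tests with median centring or without a whole line, list tests between the M lines, and counts between M lines without a fold minimum. Chromosome medians used the gene order of the mouse reference table (GRCm38.p6), for order only. The array annotation names no genome build, so no coordinates are given.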

Results

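The data were 10 arrays of cultured mouse mammary tumour cells, 2 from the epithelial line E and 2 from each of the mesenchymal lines M1, M2, M3 and M4, which came from tumours that relapsed after injection of E cells. The arrays of a line correlated at 0.992 to 0.993 across probe sets, and arrays of different lines at 0.873 to 0.976 with a median of 0.959. The first principal component held 64.7% of the variance. Signal levels differed between arrays: 36.3% of probe sets lay above a signal of 100 on E replicate 1 and 29.9% on M4 replicate 1. The ratio of 3' to 5' signal for Actb ran from 1.16 on the M1 arrays to 1.38 on M3 replicate 2, and that for Gapdh from 0.77 to 0.85.

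The first comparison asked how the relapsed mesenchymal lines differed from the epithelial line from which their tumours were grown. The M lines had lower signals of all 34 epithelial adhesion and polarity genes and higher signals of 21 of 31 mesenchymal and matrix genes. Epcam, an adhesion molecule of epithelial cells, had a signal of 10360 ± 445 (SD, n = 2) in E and between 2.2 and 3.5 in the 4 M lines, a log2 change of -8.21 ± 0.14 (SE). Cdh1, the adherens junction cadherin, fell by 5.86 ± 0.14, and Cdh2, the cadherin typical of mesenchymal cells, rose by 4.53 ± 0.13. S100a4, a calcium-binding protein of motile cells, went from 9.9 ± 1.8 in E to between 10206 and 13806 in the M lines, a rise of 8.15 ± 0.08.

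Of 14840 genes, 3233 were called in the mean of the 4 M lines against E, 1071 higher and 2162 lower (limma). Under the deposited scaling the median gene changed by -0.21, so the split between higher and lower depended on the scaling. After quantile normalization the median change was 0.04 and 2719 genes were called, 1406 higher and 1313 lower; 2383 genes were called in the same direction under both, 1071 higher and 1312 lower. In the fit to 5 line means, 1584 genes were called. Of the 107 genes named for this contrast, 100 were called and 76 of these had an adjusted p under the threshold on 5 line means.

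The 12 largest rises were at least 6.52 on the log2 scale. After S100a4 they were Lgals1 (7.60 ± 0.07), which encodes galectin-1, Ptgs2 (7.47 ± 0.10), the inducible prostaglandin synthase, Dcn (7.32 ± 0.10), which encodes the matrix proteoglycan decorin, Htra1 (6.99), Lox (6.98), a collagen cross-linking oxidase, Cav1 (6.87), Crabp2 (6.67), Cd34 (6.66), Glipr1 (6.61), Igfbp6 (6.53) and Mt2 (6.52). The 12 largest losses were Pglyrp1 (-8.55 ± 0.14), an innate immune protein, Epcam, Wfdc18 (-8.19), Cnmd (-7.94), St8sia6 (-7.74), Cd177 (-7.73), the protease inhibitor gene Spint2 (-7.71), Gpx2 (-7.70), Atp1b1 (-7.68), the tight junction claudin Cldn3 (-7.54), Fxyd3 (-7.45) and Cldn7 (-7.35). The losses had signals of 59.4 or less in the M lines and the rises 56.1 or less in E, so their sizes and ranks depend on the pseudocount of 32. By the rule that chose them, all 24 were called in each of the 4 lines. Their adjusted p on 5 line means was at most 0.000721 (limma). Small values were likely there, since the genes were chosen from the same data for large changes shared by the 4 lines.

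All 34 measured genes of epithelial adhesion and polarity fell, with a mean log2 change of -4.37. Scaling to the hybridization controls left 33 of them called. Spint2, Cldn3, Cldn7 and Epcam changed most. The list passed limma's camera (adjusted p = 2.36e-25), also with an estimated correlation (adjusted p = 0.0365), and was the only one of the 23 lists to hold there under the deposited scaling. That second call was lost with the mean of probe sets (adjusted p = 0.0816), without any single array of M2 or M4 (0.06 to 0.148) and without the whole of M2 (0.142) or M4 (0.0613).

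Of 16 luminal genes, 13 fell, 1 rose and 2 were not called. Those that fell included Krt18 (-7.33 ± 0.13), Krt7 (-7.28) and Elf5 (-7.17), a transcription factor of the secretory lineage. The gene that rose was Esr1, the oestrogen receptor (2.37), named after its value was seen. Camera called the list (adjusted p = 4.8e-09), but its adjusted p was 0.073 with an estimated correlation and 0.0296 with an estimated correlation after quantile normalization; with an estimated correlation the list was also called with the replicate block (0.0278) and without any array or the whole of M1 or M3 (0.0124 to 0.016). The keratin partners Krt8 and Krt18 separated. Krt18 fell in each line, with changes of -4.45 in M1, -8.11 in M2, -8.35 in M3 and -8.42 in M4. Krt8 fell by 6.49 in M1, while its changes were -0.01 in M2, -0.52 in M3 and -0.80 in M4. The call of Krt8 in the mean contrast (-1.96 ± 0.10) rested on M1, and its adjusted p on 5 line means was 0.634 (limma).

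Of 14 basal and myoepithelial genes, Mylk (2.35) and Acta2 (2.06), both of the contractile apparatus, rose, Lamb3 (-3.36) and Itga6 (-1.01) fell, and 10 were not called (camera adjusted p = 0.349). Itga6 lay at the fold limit. It was not called after quantile normalization (-0.69), without E replicate 1 (-0.91), without M2 replicate 2 (-0.96) or without M4 replicate 1 (-0.996). Nor was it called with the larger pseudocount (-0.95), median centring (-0.835), the mean of probe sets (-0.99) or scaling to the hybridization controls (-0.69). Krt14, a basal keratin, had signals of 13.2 to 20.2 in all 5 lines and a change of 0.11 ± 0.17.

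Of 31 mesenchymal and matrix genes, 21 rose, 4 fell and 6 were not called. The largest rises were S100a4, Dcn, Lox and the receptor tyrosine kinase gene Axl (5.51 to 6.64 in the 4 lines), and Fn1, encoding fibronectin, rose by 2.36 ± 0.10. The 4 that fell were the basement membrane collagens Col4a1 (-5.93) and Col4a2 (-5.15), Mgp (-2.82) and Tnc (-1.37, not called after quantile normalization), all 4 named after their values were seen. Vim, the intermediate filament of mesenchymal cells, was already at 9644 ± 475 (SD, n = 2) in E and changed by 0.31 ± 0.06, below the fold limit. As a list they passed camera (adjusted p = 1.47e-17); the adjusted p was 0.199 with an estimated correlation.

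Among 16 EMT transcription factors, 9 rose, 3 fell and 4 were not called. Twist2 (5.11 ± 0.14), Snai2 (4.93 ± 0.13), Prrx1 (4.55 ± 0.13) and Zeb1 (4.45 ± 0.13), repressors or activators that drive the loss of epithelial traits, rose most, from signals of 5.8 to 14.7 in E. Zeb2 rose by 2.27 ± 0.15. Snai1 (1.53 ± 0.15) and Twist1 (1.23 ± 0.16) rose less, and on 5 line means their adjusted p was 0.317 and 0.0595 (limma). Both lay near the background: with values below 64 set to 64 their changes were 0.72 and 0.16, and neither was called there or with the larger pseudocount. The 3 that fell were Id1 (-2.96) and Id2 (-3.27), which encode inhibitors of helix-loop-helix factors, and Snai3 (-1.19, not called after quantile normalization), named after their values were seen. The list passed camera (adjusted p = 0.00136), with an adjusted p of 0.595 with an estimated correlation and a camera adjusted p of 0.109 after quantile normalization and 0.0552 with scaling to the hybridization controls.

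**Figure D1:**
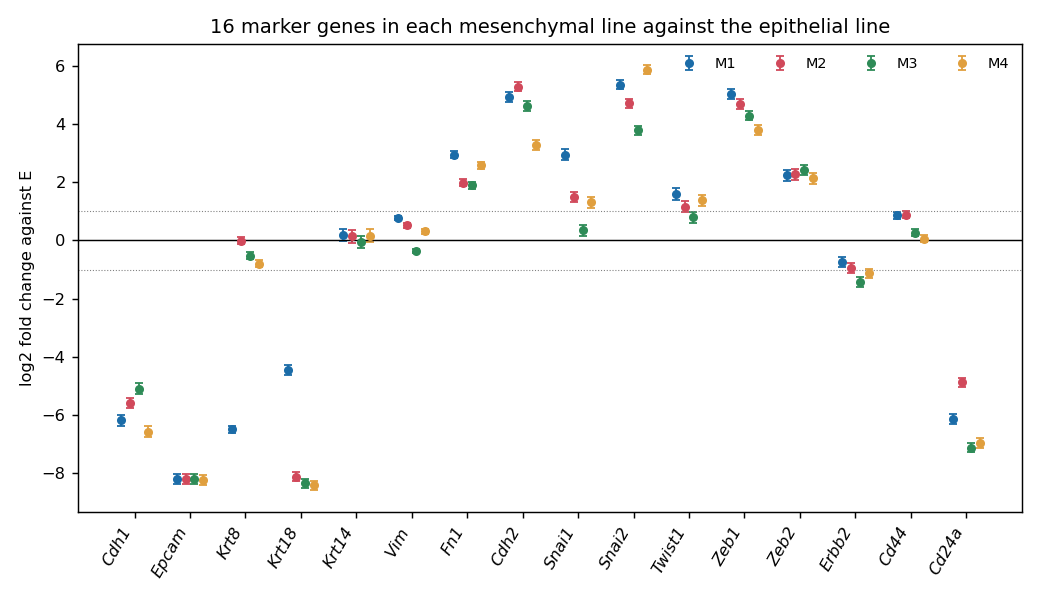
Log2 fold change of 16 marker genes in each mesenchymal line against E, with bars for the standard error (2 arrays per line) and dotted lines at a change of 1 in either direction. Epcam, Cdh1, Cd24a and Krt18 lie below -4 in every line, Krt8 does so only in M1, and Cdh2, Snai2 and Zeb1 lie above 3 in every line.

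Since E carried neu as its oncogene, the ERBB genes were examined as a list. Of 15 receptors and ligands, 5 fell, 2 rose and 8 were not called (camera adjusted p = 0.411). Erbb3, the partner receptor of neu, fell by 4.83 ± 0.13, its relatives in the pathway Tgfa (-4.59), Grb7 (-3.10) and Hbegf (-2.17) fell too, and the ligands Ereg (1.53) and Nrg1 (1.58) rose (named after their values were seen). The Erbb2 signal was 318 ± 4.0 (SD, n = 2) in E and 97.4 to 178 in the M lines. Its change of -1.06 ± 0.13 was called under the deposited scaling only, and was -0.65 after quantile normalization, with an adjusted p of 0.127 on 5 line means (limma). Under the deposited scaling it was not called with the larger pseudocount (-0.75). Whether this probe set also reads the transgene is not given in the sources used here.

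Of 18 stem and progenitor markers, 10 fell, 2 rose and 6 were not called. Cd24a, a surface marker of luminal cells, fell by 6.27 ± 0.13, Kit by 5.18 and the transporter gene Abcg2 by 4.45, while Klf4 rose by 5.59 ± 0.13. The other gene that rose was Procr (4.07), named after its value was seen. Cd44, often used with Cd24a to sort mammary cells, changed by 0.52 ± 0.09 and was not called; of its 2 other probe sets, 1 was called (1.06) and 1 was not (0.86). Together they passed camera (adjusted p = 0.0176), with an adjusted p of 0.595 with an estimated correlation. The call was lost without M2 replicate 1 (adjusted p = 0.0822), M2 replicate 2 (0.052) or the whole of M2 (0.0614), and with the mean of probe sets (0.0513).

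Of 17 genes of MHC class I antigen presentation, 4 rose, none fell and 13 were not called; after quantile normalization 7 rose. At an unadjusted p under 0.05 and no fold minimum, limma had 8 higher and 3 lower. Psmb8, a subunit of the immunoproteasome, rose by 4.94 ± 0.13, H2-M3 by 2.61, Psmb9 by 1.33 and the regulator gene Nlrc5 by 1.15. Psmb9 and Nlrc5 had adjusted p of 0.14 and 0.429 on 5 line means (limma) and were not called with the larger pseudocount (0.85 and 0.58); Nlrc5 was not called with values below 64 set to 64 either (0.71). The list passed camera (adjusted p = 0.00281), with an adjusted p of 0.667 with an estimated correlation. Of 33 interferon response genes, 11 fell and 3 rose (8 and 5 after quantile normalization), among them Ifi47 (2.99) and Gbp2 (2.29), which rose, and Rtp4 (-2.99) and the transcription factor gene Irf9 (-2.35), which fell (camera adjusted p = 0.349).

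Genes of matrix remodelling rose together: 15 of 23 proteases and inhibitors rose, none fell and 8 were not called (1 was lower at an unadjusted p under 0.05 in limma without a fold minimum). Timp1 (5.28 ± 0.11), Mmp13 (5.26 ± 0.13), Mmp10 (4.95 ± 0.13) and Timp3 (4.65 ± 0.14) rose most; Mmp13 rose by only 1.58 in M1 and had an adjusted p of 0.163 on 5 line means (limma). This group passed camera (adjusted p = 1.75e-14), with an adjusted p of 0.199 with an estimated correlation (0.011 after quantile normalization). Of 24 cytokines and chemokines, 11 rose and 4 fell. Ptgs2 led, followed by the monocyte attractants Ccl7 (5.54 ± 0.11) and Ccl2 (4.34 ± 0.08), while Ccl20 fell by 3.77. Camera called the cytokine list (adjusted p = 4.28e-05), with an adjusted p of 0.583 with an estimated correlation.

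Of 26 TGF-beta genes, 7 rose and 8 fell, with Tgfbi (5.81) up and Bambi (-4.32), Tgfb2 (-3.55 to -4.39 in the 4 lines) and Pmepa1 (-3.68) down. This list's median (-0.41) and mean (-0.36) were below 0 and below the median of all genes (-0.213). Its camera test, which works on t statistics and not on log2 changes, was in the upward direction, with no call (camera adjusted p = 0.892). Of 22 Wnt genes, 5 rose and 8 fell (adjusted p = 0.892). The ligands Wnt7b (-4.57) and Wnt5b (-3.16) and the secreted inhibitors Wif1 (-4.25) and Sfrp1 (-4.13) changed most. Among 13 drug efflux transporters, 3 rose and 3 fell (adjusted p = 0.314); Abcc4 (4.81) and Abcb1b (3.72), which encodes a P-glycoprotein, rose, and Abcg2 and Abca3 (-2.27) fell. Of 21 genes of glycolysis and hypoxia, 4 rose and 3 fell (adjusted p = 0.591), with Ndrg1 (5.39) and Bnip3 (2.59) up and Pfkp (-2.35) and Hk1 (-1.60) down. For the efflux (-0.119), glycolysis (-0.129) and skeletal muscle (-0.078) lists the median was below 0 and the test was upward. Unlike that of the TGF-beta list, these medians lay above the median of all genes, and none of these lists was called.

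Cell-cycle genes were lower in the mean contrast: 18 of 30 fell under the deposited scaling and 6 after quantile normalization. Those with the largest change were Mki67 (-2.11 ± 0.12), Rrm2 (-1.64), Mcm4 (-1.47) and Ccnb2 (-1.46). The list passed camera (adjusted p = 1.14e-07), with an adjusted p of 0.595 with an estimated correlation (0.00738 after quantile normalization), 0.27 without line M3 and 0.265 on 5 line means. Of 27 DNA repair genes, 7 fell (2 after quantile normalization), among them Ercc1 (-2.73), Lig3 (-1.89), Chek1 (-1.39) and Lig1 (-1.33), and the last pair were not called after quantile normalization, nor Chek1 with the mean of probe sets (-0.71); 3 of the 5 Chek1 probe sets were not called. Their list passed camera (adjusted p = 0.0299), with an adjusted p of 0.778 with an estimated correlation. The DNA repair call was lost when E replicate 2 or any single array of M1, M3 or M4 was left out, with adjusted p from 0.0529 (without M4 replicate 1) to 0.174 (without M1 replicate 2), and also after quantile normalization (0.0732), with the replicate block (0.0926), on 5 line means (0.265) and without the whole of M1, M3 or M4 (0.0721 to 0.308). Of 16 CDK inhibitors and p53 targets, 6 fell, including Perp (-2.27), Cdkn1b (-2.22), Btg2 (-1.89) and Ei24 (-1.64), and 3 rose (adjusted p = 0.349).

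Markers of other cell types were examined for cells that a tumour-derived culture could carry. Of 12 stromal fibroblast markers, 7 rose and 1 fell (0 after quantile normalization). They included Dcn, Pdgfra (4.37), Gsn (3.78) and Mfap5 (2.40), and the list passed camera (adjusted p = 5.73e-07) with an adjusted p of 0.171 with an estimated correlation. This list shares 3 of its 12 genes with the matrix list; all 3 rose, as did 4 of the other 9. Of 16 leukocyte markers, Itgb2 (2.46) and Coro1a (1.37) rose and none fell (2 were lower at an unadjusted p under 0.05 in limma without a fold minimum), and 4 of the 16 exceeded a signal of 100 in any M line mean. Coro1a was not called with the smaller pseudocount (0.23), the larger one (0.52), values below 64 set to 64 (0.18) or the mean of probe sets (0.78), and its other probe set changed by 0.19. The leukocyte list passed camera (adjusted p = 0.0263), with an adjusted p of 0.247 with an estimated correlation; the call was lost without E replicate 1, M4 replicate 1 or any array of M1 or M3 (adjusted p from 0.0519 without M4 replicate 1 to 0.155 without M3 replicate 2), after quantile normalization (0.109), with the replicate block (0.0926) or without the whole of M1, M3 or M4 (0.0697 to 0.224). None of 11 endothelial and 4 adipocyte markers was called by limma (camera adjusted p = 0.349 and 0.411). Without the fold minimum, an unadjusted p under 0.05 was reached by 1 higher and 1 lower endothelial marker, Eng (0.34) and Plvap (-0.87), and by 2 higher and 1 lower adipocyte marker, with the smallest p for Lpl (0.85) and Slc2a4 (-0.995). Slc2a4 was called without E replicate 2 (-1.04), M1 replicate 2 (-1.10), M2 replicate 2 (-1.08), M3 replicate 2 (-1.01) or M4 replicate 2 (-1.02). It was also called with the smaller pseudocount (-1.62), as was Plvap (-1.90), and with the mean of probe sets (-1.21), and its other probe set was called (-1.43). Lpl was called with median centring (1.03) and with scaling to the hybridization controls (1.17). Of 9 skeletal muscle markers, Tnni2 (-1.45) fell (camera adjusted p = 0.752), but was not called with values below 64 set to 64 (-0.44) or with the larger pseudocount (-0.61).

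Other counts that moved after quantile normalization were those of the ERBB (3 rose and 4 fell), TGF-beta (9 and 7), efflux (4 and 2), CDK inhibitor (3 and 5), cytokine (11 and 3), luminal (1 and 12), basal (2 and 1), stem (2 and 9), matrix (21 and 3), EMT (9 and 2) and protease (16 and 0) lists. In all 23 lists, the counts adjusted over the list alone were identical to those over all genes tested. By limma's camera 12 of the 23 lists were called in the mean contrast, 9 of them also after quantile normalization. By fry 18 were called. The estimated correlations were themselves lower after quantile normalization in every list except the leukocyte markers.

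**Figure D2:**
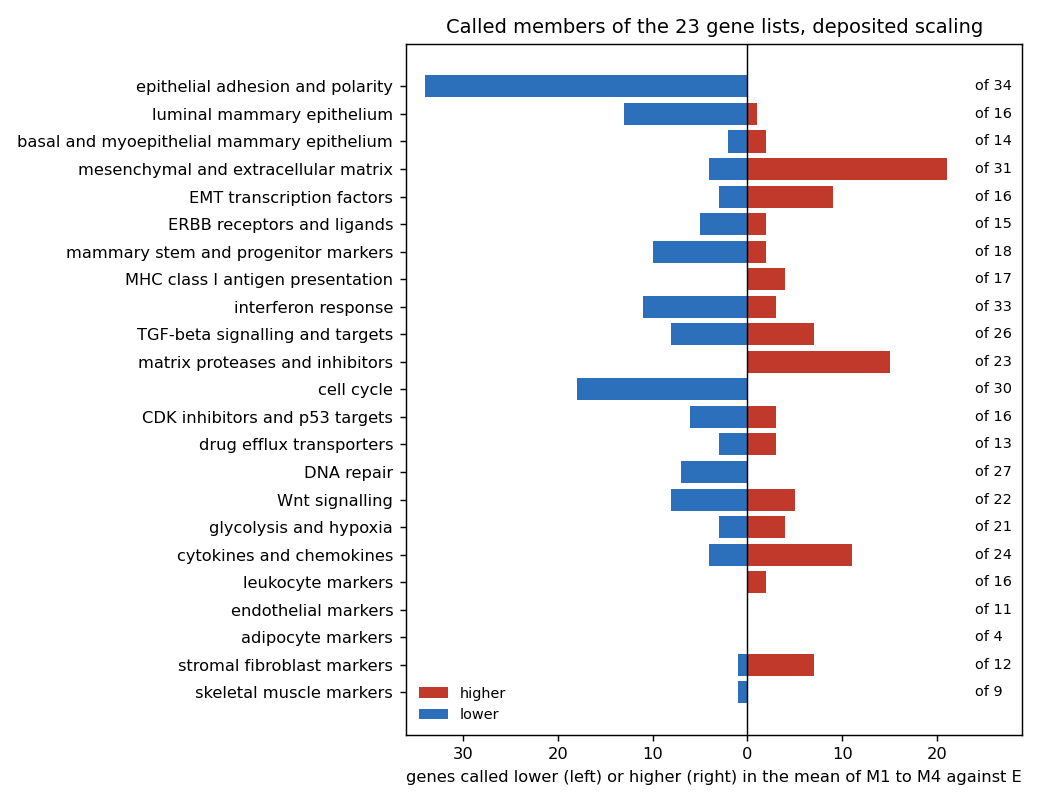
Number of genes called lower (left) and higher (right) in the mean of the 4 mesenchymal lines against E in each of the 23 lists, under the deposited scaling, with the number measured at the right. Epithelial adhesion has 34 of 34 lower, matrix genes 21 of 31 higher and proteases 15 of 23 higher; cell-cycle genes have 18 of 30 lower here and 6 of 30 after quantile normalization.

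The next question was how much the 4 M lines had in common. A shared set of 1965 genes was called in the same direction in all 4 lines against E, 617 higher and 1348 lower. After quantile normalization there were 840 higher and 905 lower, and 1521 genes were in both sets. The lines share their comparison with E, which alone makes their changes correlate. In simulations of unchanged lines the mean correlation of changes was 0.5 to 0.501 for each pair of lines, against 0.858 to 0.918 observed. The mean simulated covariance was 0.0162 against 1.34 to 1.42 observed, and the highest count of genes called in all 4 lines was 0 in 100 simulated data sets. The simulated lines varied only by the spread between arrays, so a count of 0 was to be expected and measures no difference between separate lines. Part of the excess may come from the shared E line. Independent lists of the observed sizes would share 0.522 higher and 8.94 lower genes.

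Line by line, 3125 genes were called in M1 against E (1257 higher, 1868 lower), 3012 in M2 (1247 and 1765), 4080 in M3 (1124 and 2956) and 3967 in M4 (968 and 2999). The median change of all genes was -0.11 in M1, -0.14 in M2, -0.26 in M3 and -0.35 in M4. After quantile normalization the counts were 2885 (1486 and 1399), 2771 (1467 and 1304), 3502 (1763 and 1739) and 2928 (1515 and 1413). Epithelial adhesion genes fell in each line, 32 of 34 in M1 and 34 of 34 in the other 3, with adjusted p of 0.0288, 0.0242, 0.0479 and 0.0372 with an estimated correlation. Of 31 matrix genes, 21 rose in M1, M2 and M4 and 18 in M3, while 4 fell in each line (after quantile normalization 20 rose in M3, and 3 fell in each of the others), with adjusted p of 0.263, 0.212, 0.139 and 0.276 with an estimated correlation for M1, M2, M4 and M3. Of 92 tests of 23 lists in 4 lines, 44 passed camera and 5 of them also held with an estimated correlation; the fifth was the luminal list in M1 (adjusted p = 0.035).

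The last question was how the M lines differed from each other. M3 stood apart by its cell-cycle genes, all 30 of which were lower than in the mean of the other M lines (29 after quantile normalization). The signal of Mki67, the proliferation antigen, was 3216 ± 242 (SD, n = 2) in E, 1704 ± 40 in M1, 1383 ± 399 in M2, 955 ± 6.9 in M4 and 102 ± 0.3 in M3. The thymidine kinase gene Tk1 was lower in M3 than in the others by a log2 change of -4.09 ± 0.12. The median change of the list against E was -0.29 in M1, -0.56 in M2, -3.00 in M3 and -0.71 in M4, and after quantile normalization -0.19, -0.34, -2.53 and -0.15. Against the other M lines the M3 list passed camera (adjusted p = 3.91e-49), with an adjusted p of 0.335 with an estimated correlation and 0.00113 with an estimated correlation after quantile normalization. The M3 arrays had the highest Actb 3' to 5' ratios of the 10, 1.29 and 1.38, but the lowest Gapdh ratios, 0.79 and 0.77.

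Against the other M lines the glycolysis and hypoxia list had a median of 0.71 in M1 (0.43 after quantile normalization), -0.26 in M2 (-0.38), -0.28 in M3 (-0.23) and -0.04 in M4 (0.215). Of its 21 genes, 7 were called higher and 0 lower in M1 (2 and 1 after quantile normalization), and under both scalings 0 higher and 3 lower in M2, 1 and 0 in M3, and 1 and 1 in M4. The camera adjusted p was 5.98e-09 in M1, 1.11e-11 in M2, 0.141 in M3 and 0.899 in M4; in M1 and M2 it was 0.525 and 0.59 with an estimated correlation, and 0.0168 and 0.00896 with an estimated correlation after quantile normalization. The list tests between M lines were chosen after the data were seen.

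**Figure D3:**
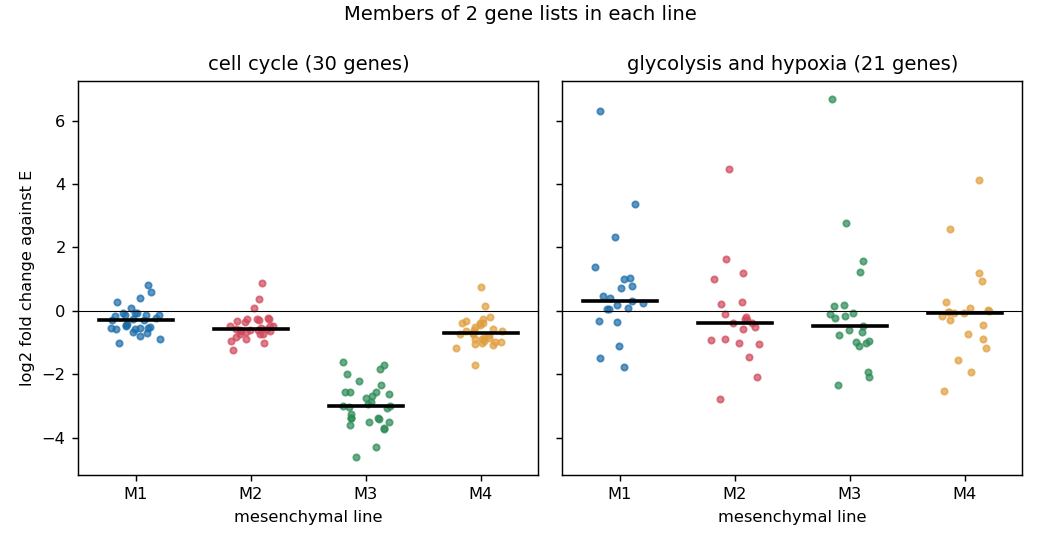
Log2 fold change against E of the 30 measured cell-cycle genes (left) and 21 glycolysis and hypoxia genes (right) in each mesenchymal line, 1 point per gene, with a black bar at the median, under the deposited scaling. The cell-cycle median is -3.00 in M3 and between -0.71 and -0.29 in the others, and the glycolysis median is 0.32 in M1, -0.37 in M2, -0.47 in M3 and -0.06 in M4.

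In numbers, 664 genes differed between M1 and M2, 1618 between M1 and M3, 1319 between M1 and M4, 1070 between M2 and M3, 921 between M2 and M4 and 1519 between M3 and M4. Leaving out M2 replicate 2 changed the count between M2 and M4 to 1521, and after quantile normalization the 6 counts were 647, 1419, 891, 888, 602 and 1545. The moderated F test called 3283 genes across the 4 lines (2677 after quantile normalization).

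Against the mean of the other 3 lines, 787 genes were called in M1, 358 in M2, 982 in M3 and 809 in M4; without M2 replicate 2 the count for M2 was 555, and after quantile normalization the 4 counts were 631, 273, 970 and 657. The split turned with the scaling in M1, from 538 higher and 249 lower to 289 and 342 after quantile normalization. In M4 it turned from 222 and 587 to 348 and 309. It kept its side in M2 (280 and 78, then 154 and 119) and M3 (286 and 696, then 413 and 557). Under the deposited scaling, genes called against the other 3 together and against each of them separately numbered 149 higher and 99 lower in M1, 56 and 2 in M2, 74 and 354 in M3, and 101 and 164 in M4. In M1 the matrix gene Efemp1 was highest (6.90 ± 0.15, with a signal of 4899 ± 490 (SD, n = 2) in M1 and 5.3 ± 0.4 in M3), followed by Krt18 (3.85) and Mbnl3 (3.23), while Krt8 (-6.05), Rhox5 (-5.51) and Mmp13 (-4.92) were lowest. In M2 the highest were Cck (5.40 ± 0.15), which encodes cholecystokinin, Slc14a1 (3.86), a urea transporter gene, and Padi4 (3.45). The 2 lower genes of M2 were the cystine transporter gene Slc7a11 (-1.24) and the hexokinase gene Hk2 (-1.18), neither of them called without M2 replicate 2 (-0.93 and -0.96), nor Slc7a11 with the larger pseudocount (-0.63), values below 64 set to 64 (-0.96) or the mean of probe sets (-0.90). In M3 the highest were Vnn1 (5.04 ± 0.14), Car6 (4.99 ± 0.14), a secreted carbonic anhydrase gene, and Avil (4.63), and the lowest were the fibrillar collagen gene Col3a1 (-4.24), Tk1 and Tspan11 (-3.94). In M4 the highest were U90926 (6.32 ± 0.16), the interferon-inducible gene Ifitm1 (5.30) and Thbs2 (5.04), and the lowest were Perp (-3.63), Pkia (-3.58), an inhibitor of protein kinase A, and Socs2 (-3.57), a suppressor of cytokine signalling. Each of these had a limma adjusted p of 6.93e-09 or less.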

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

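The list tests between the mesenchymal lines and the test of the scaling of the M3 arrays were chosen only after the result was seen; the tests of RNA quality and of dividing cells were not.

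In 39 genes, 2 mesenchymal lines were called in opposite directions against E, and limma also called the difference between the lines in these genes, as the way they were chosen made certain; 35 genes were opposite after quantile normalization and 20 were so under both scalings. Among the genes named in the report, Car6 differed by 4.99 in M3 against the other 3 mesenchymal lines, having risen by 2.96 against E in M3 while it changed by -3.01 in M2 and -2.37 in M4. Padi4 differed by 3.45 in M2 against the other 3, with changes against E of 2.25 in M2 and -2.10 in both M1 and M4. Pkia differed by -3.58 in M4 against the other 3, with changes against E of 1.07 in M1 and -2.83 in M4. Other genes of this kind, chosen here after their values were seen, were the alarmin S100a8 (3.03 in M4 and -1.97 in M1), Il33 (3.80 in M4 and -1.64 in M3), the stress gene Gadd45a (1.39 in M1, 1.87 in M3, -1.25 in M2 and -1.48 in M4) and Txnip (1.09 in M3, -1.67 in M1, -1.36 in M2 and -1.58 in M4).

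Against the other 3 mesenchymal lines the median log2 change of the cell-cycle list after quantile normalization was -2.425 in M3, 0.82 in M1, 0.60 in M2 and 0.88 in M4; each of the last 3 values has M3 among the lines it is set against. The scaling of the M3 arrays is excluded as the whole cause, since the median under the deposited scaling, -2.61, became -2.425 after quantile normalization. The test of RNA quality compared only the 2 M3 arrays: replicate 2, with the higher Actb ratio, differed from replicate 1 by a median of only -0.029. An effect that grew with the Actb ratio between these arrays is argued against. Poorer RNA on both cannot be judged by it, since both had high Actb ratios (1.29 and 1.38) and may come from the same RNA. Whether fewer cells were dividing in the M3 cultures cannot be told apart from other causes: the medians of 9 DNA replication genes (-1.948) and 14 mitosis genes (-2.425) decide nothing, since 29 of the 30 genes of the list were called lower.

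The glycolysis and hypoxia list had a median after quantile normalization of 0.43 in M1, -0.38 in M2, -0.23 in M3 and 0.215 in M4 against the other 3 mesenchymal lines.

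Probe sets with no symbol or several symbols were outside the gene tests. Of 5556 that passed the filter, 481 were called between the mesenchymal lines and E, 152 higher and 329 lower, and 84 and 168 were called so in all 4 lines.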

How the results depend on the processing

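Scaling to the hybridization controls, the list tests with median centring or without a whole line, and the counts among M lines without a fold minimum, were chosen only after the result was seen; all other alternatives were fixed before the data were examined. Except where named here, each total of genes or lists called that was computed under an alternative stayed within 1.5 times the reported value. For the comparisons of 2 M lines or of 1 with the other 3, the larger pseudocount, the floor of 64, the stricter filter and p, the other choices of probe set and the variance priors were not run. The split into higher and lower genes moved further: after quantile normalization the lower genes went from 2162 to 1313 in the mean contrast and from 2999 to 1413 in M4.

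Without a fold minimum the counts were 9015 for the mean of the M lines against E, 7469 for M1, 7511 for M2, 8627 for M3, 8936 for M4, 4550 for all 4 lines together and 8968 for the F test, since the call then needs less; they were 3482 (M1 and M2), 5792 (M1 and M3), 6048 (M1 and M4), 4699 (M2 and M3), 5219 (M2 and M4) and 5471 (M3 and M4) between lines, and 5523 (M1), 3914 (M2), 5592 (M3) and 5744 (M4) against the other 3. With a pseudocount 4 times as large, which shrinks changes of weak signals, they were 2078 for the mean, 2049 for M1, 1969 for M2, 2465 for M4, 1259 for all 4 and 1822 for the F test. With a pseudocount of 1, which widens them, the differences between lines became 1033 (M1 and M2), 2448 (M1 and M3), 2110 (M1 and M4), 1671 (M2 and M3), 1629 (M2 and M4) and 2301 (M3 and M4), and those against the other 3 lines became 1376 (M1), 768 (M2), 1687 (M3) and 1478 (M4). Quantile normalization gave 602 for M2 against M4, and the cause was not tested. The fit to 5 line means gave 1584, with fewer degrees of freedom. With an estimated correlation, 1 list was called in the mean contrast and 5 in the single lines. The estimated correlation itself depended on the scaling. From the deposited scaling to quantile normalization it went from 0.743 to -0.00183 for MHC class I, from 0.713 to -0.0145 for cell cycle and from 0.406 to 0.105 for matrix genes. Only that of the leukocyte list rose, from 0.0189 to 0.0256. The adjusted p with an estimated correlation therefore depends on the scaling too. By fry 68 were called in the single lines. By camera 9 lists were called in the mean contrast after quantile normalization and 10 or 11 with 1 array left out.

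Leaving out 1 array in turn, the lone array of a line being assumed to vary like the other lines, gave 3076 to 3532 genes for the mean contrast, 661 to 1521 between M2 and M4 and 263 to 555 for M2 against the other 3. The 1521 and the 555 came without M2 replicate 2. Without a whole line the mean contrast gave 3438 (M1), 3422 (M2), 3098 (M3) and 3207 (M4) genes, and with line as a random block 2708.

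The replicate numbers did not pair the arrays: the 10 correlations between lines of the difference of replicates ran from -0.069 to 0.058 across genes. With the replicate block 3233 genes were called in the mean contrast, all 3233 in the same direction as without it, and no named gene changed its call.

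Of 130 results for named genes, 123 were calls, of which between 114 (the larger pseudocount) and 123 were kept under each alternative run on the named genes, and none reversed. The random block was not run on them; on 5 line means 76 of the 100 calls in the mean contrast had an adjusted p under the threshold. Genes with weak signal in both groups are limited by the background of the arrays.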

Other observations

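All tests in this part were chosen only after the result was seen, except the test of chromosome medians among genes not called.

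Against the other 3 mesenchymal lines, 10 of 31 matrix genes were lower in M3 (8 after quantile normalization) and 1 was higher, while in M4 10 were higher and 1 was lower; in M1 6 were higher and 4 lower (5 and 6 after quantile normalization), and in M2 5 and 4 (2 and 4). Of 12 stromal fibroblast markers, 4 were lower and 1 higher in M1 (6 and 1 after quantile normalization), 1 was lower in M2, 4 were lower and 1 higher in M3 (3 and 1), and 1 was lower and 4 higher in M4. The camera adjusted p for the matrix list was 2.43e-09 in M3 and 2.66e-09 in M4, with adjusted p of 0.708 and 0.592 with an estimated correlation. Interferon response genes had a median of 0.39 in M3 (0.49 after quantile normalization), where 4 of 33 were higher under both scalings, and of -0.37 in M4 (-0.215), where 6 were lower (2 after quantile normalization), with adjusted p of 0.727 and 0.862 with an estimated correlation. MHC class I genes had a median of 0.33 in M3 (0.34 after quantile normalization), where 1 of 17 was higher, and of -0.67 in M4 (-0.39), where 2 were lower (1 after quantile normalization), with adjusted p of 0.767 and 0.862 with an estimated correlation. At the preset correlation camera called the interferon list in M3 (adjusted p = 3.99e-05) and M4 (0.0065). It also called the MHC class I list in M3 (0.0223) and M4 (0.000115). After quantile normalization these calls stayed. With an estimated correlation after quantile normalization the camera adjusted p was 0.0548 and 0.0911 for interferon, and 0.0824 and 0.0911 for MHC class I.

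Of 80 chromosome medians (20 chromosomes in 4 lines, 7411 genes, relative to all genes), 28 lay beyond every one of 1000 shuffles of the genes. Genes on chromosome 2 were lower in every mesenchymal line against E (-0.63 in M1, -0.53 in M2, -0.64 in M3 and -0.35 in M4), and genes on chromosome 4 were higher (0.57, 0.41, 0.44 and 0.43). Chromosome 3 was higher in M1, M2 and M3 (0.26, 0.25 and 0.54), chromosome 15 in M1, M2 and M4 (0.59, 0.19 and 0.36), and chromosome 8 was lower in M4 only (-0.30).

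Medians were taken relative to all genes, which removes a factor common to an array, so only scaling that depends on signal was tested. It is argued against for 27 of the 28 medians. These stayed beyond the shuffles after quantile normalization and kept their sign in each of 3 equal groups of genes by signal. The sign alone adds little, since many medians within the shuffles kept theirs in all 3 groups too. For chromosome 7 in M3 the bar set by the shuffles cannot tell. Its median hardly moved (-0.216 before and -0.215 after) and kept its sign in all 3 groups, while the highest shuffle went from 0.205 to 0.216. A few strongly changed genes are argued against for 16 medians that stayed beyond the shuffles among genes not called, while for the other 12, which fell within the shuffles there (-0.041 against -0.354 among all genes for chromosome 2 in M4), a shift of the called genes and one of the whole chromosome cannot be told apart, since the change itself decides which genes that filter leaves. Whether gene dosage lies behind the shifts cannot be told apart from other causes: all 28 medians had their sign in at least 3 of 4 equal parts of the chromosome in gene order, but so had 48 of the other 52, and no DNA was measured. The SD of the chromosome differences was 0.075 between M2 and M3 and 0.181 to 0.218 for the other 5 pairs; whether M2 and M3 share their dosage cannot be told apart either, and a shift shared by all 4 lines may equally belong to E.

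The loss of epithelial and the rise of mesenchymal transcripts was set against cells of another type. An admixture that leaves most of the RNA epithelial is argued against. The epithelial genes had a median of -3.71 or lower in every line relative to all genes. That would need at least 92.4% to 93.3% of the RNA from other cells. These shares are lower limits, since the pseudocount shrinks falls to weak signals. Genes that fell further than the median, Epcam among them, would need a larger share. Such a larger share, up to full replacement, is not excluded, since the values are those of the loss itself. Whether the M lines could be host cells in place of descendants of E cannot be told apart. In all 6 pairs of lines the chromosome medians differed beyond every shuffle, but this does not decide it. Such shifts could not be tied to gene dosage, no DNA was measured, and host cells may change in culture. Of the stromal fibroblast markers 7 of 12 rose in the mean contrast, and of the 9 that are not also in the matrix list 4 rose; no test here separates a change of E cells from outgrowth of such cells.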
